A study of Mus musculus with 27 samples.

How the data were processed

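Gene expression was measured by RNA sequencing of polyA RNA in cardiac myocytes, endothelial cells and fibroblasts isolated from the hearts of male C57Bl6N mice, 8 to 10 weeks old per the labels. The mice had transverse aortic constriction (TAC), in which the aorta is tied around a 26-gauge needle so that the left ventricle pumps against a higher pressure, or a sham operation without the ligature. Cells were collected 1 week or 8 weeks after TAC. Each of the 3 cell types had 3 sham, 3 TAC 1 week and 3 TAC 8 weeks libraries, 27 in all, and every library was placed in its group from its label. The labels do not state when after surgery the sham hearts were collected, whether the 3 cell types came from the same hearts, or whether a replicate is 1 animal or a pool. The p-values therefore measure the spread between these libraries, and time after TAC has no sham group of its own.

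The submitters' notes name Trim Galore, STAR, featureCounts and edgeR with genome build mm10, without versions. The authors deposited 6 tables, each comparing TAC at 1 time with sham in 1 cell type, with 20105 genes in every table. The deposited sample columns are log2 values: within each library the back-transformed values were whole multiples of the lowest value, for 100% of values within a tolerance of 0.01 of a whole number. They are thus log2 of (reads + 1) times 1 scale per library, and whole reads could be recovered. The deposited scale is not the library total, since the scaled reads of a library sum to between 603328 and 1876840. The scales of all 27 libraries stand in whole-number ratios, so they were taken as set on a common scale. The sham columns were identical in the 1 week and 8 weeks tables of a cell type (largest difference 0). The tables also give the authors' log2 fold change, coded as sham minus TAC, with a p-value and an FDR from a likelihood-ratio test. Of the identifiers, 20057 are in GENCODE M21, which gave the mm10 coordinates; 16760 genes are labelled protein coding, and 5 symbols are shared by 2 identifiers each. No mitochondrially encoded gene is listed, and neither is Gapdh. In 1 column without a name, 1 cell held text, which was not used.

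Recovered reads ranged from 12925232 to 34030597 per library. Reads were multiplied by the deposited scale, without the offset of 1 read; this unit is called scaled reads. Tests used log2(scaled reads + 1) in limma 3.58.1 (R 4.3.3) with a mean-variance trend and a robust variance prior, on the 9 libraries of a cell type together. Genes with a mean of at least 1 scaled read were tested: 13033 in myocytes, 13146 in endothelial cells and 13691 in fibroblasts. The 9 comparisons were TAC 1 week with sham, TAC 8 weeks with sham and TAC 8 weeks with TAC 1 week in each cell type. P-values were two-sided and adjusted by Benjamini and Hochberg over the tested genes, and genes with an adjusted p under 0.05 were called. Fold changes are differences of means on the log2(scaled reads + 1) scale, so they are drawn toward 0 for genes with few reads. Whether a TAC effect differed between cell types was tested with an F test of the interaction in a fit of all 27 libraries (13887 genes). Values are means with the standard deviation (SD) over n = 3 libraries, and intervals for ratios of reads are 95% exact binomial intervals that cover counting error only, since the reads carry no molecular identifiers.

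The comparisons, the test, the genes to be named and 38 gene lists were fixed before the data were examined. The plan held a count model for tables of counts and limma for tables of normalized values, and the second case applied. Named genes were the 8 with the highest and the 8 with the lowest fold change against sham. For TAC 8 weeks against TAC 1 week they were 4 and 4. All were called, with a mean of at least 5 scaled reads in the higher group and libraries of the groups that did not overlap. Symbols of unnamed genes were left out. To these came a fixed panel of stress, matrix, endothelial, mesenchymal and cell cycle genes. The 4 members of each list with the lowest p in a comparison could be named as well. Under chance, 10% of genes have groups of 3 that do not overlap. For the interaction the 8 genes with the lowest p were named at each time; unnamed symbols were passed over there too, although the rule stated that only for fold changes, and this moved 1 unnamed gene out at each time. A few other genes were chosen after their values were seen and are given as such.

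The lists covered myocyte biology (hypertrophy and fetal programme, adult sarcomere, ion channels and calcium handling, fatty acid oxidation, oxidative phosphorylation, mitochondrial biogenesis regulators, glycolysis), matrix and fibroblast states (fibrillar matrix and crosslinking, basement membrane, activated fibroblast and myofibroblast, quiescent fibroblast, mesenchymal markers of endothelial to mesenchymal transition), endothelial states (identity, lipid transport, angiogenic sprouting, activation and leukocyte adhesion), general programmes (cell cycle, TGF-beta pathway, interferon response, inflammatory cytokines, immediate early genes, unfolded protein response, oxidative stress response) and markers of cell types that isolated cells could hold (myocyte, endothelial, fibroblast, pericyte and smooth muscle, macrophage and monocyte, lymphocyte, neutrophil, Schwann cell, mesothelium, lymphatic endothelium, endocardium, platelet, erythrocyte and adipocyte). The list of immediate early genes also held genes of stress from cell dissociation, heat shock genes among them. Mitochondrially encoded genes and erythrocyte and adipocyte markers never had the 5 tested members that a test needed. This left 35 lists and 200 tests over the 6 comparisons with sham. Lists were tested with camera, which compares a list with all other tested genes, with a preset correlation of 0.01, and again with the correlation estimated from the data; fry tested whether a list moved on balance in 1 direction by itself. List p-values were adjusted over the 200 tests. Of these, 121 passed with the preset correlation (66 up, 55 down) and 0 with an estimated correlation, where the lowest adjusted p was 0.171; fry passed 92. The level of each marker list in every library was compared by exact two-sided permutation tests, which with 3 libraries against 3 cannot go below 0.1. Shares of another cell type were computed as the level of that type's markers in percent of their level in the libraries of that type.

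The fit was tested on simulated data with 200 changed genes in each of 3 simulations. A fold of 2 was recovered for 84.6% of changed genes in myocytes, 90.0% in endothelial cells and 81.6% in fibroblasts, and a fold of 1.5 for 64.2%, 75.1% and 20.9%, with a mean of 13, 9.33 and 7.33 false calls. No pair of replicate libraries was a duplicate by a chi-square test of their reads. Overlaps between cell types used Fisher's exact test across genes, and overlaps between weeks were set beside 20 simulated draws in which groups that did not change shared the sham libraries.

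The alternatives were scaling by the median of ratios within the cell type, library totals, no filter or a filter of 10 scaled reads in 3 samples, a pseudocount of 0.1 or 5, no robust prior, a fit of the 6 compared libraries or of all 27, and each library left out in turn. The planned Wald test of a count model was not run, because the deposited values are not counts, and the alternative without mitochondrially encoded genes did not apply, because none is listed. Added after the data were seen were TMM scaling, voom on the recovered reads, limma on the deposited log2 columns, the authors' deposited FDR at 0.05 and leaving out replicates 2 and 3 of the fibroblasts at 8 weeks. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.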

Results

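The data describe gene expression in isolated mouse cardiac myocytes, endothelial cells and fibroblasts after sham surgery, 1 week after TAC and 8 weeks after TAC, with 3 libraries in each of the 9 groups. The series title asks whether endothelial cells pass through a transient and partial endothelial to mesenchymal transition, in which they take on mesenchymal genes, during pressure overload. Libraries of myocytes held 12925232 to 19326548 reads over 16567 to 17714 genes, those of endothelial cells 18528111 to 34030597 reads over 18712 to 19287 genes, and those of fibroblasts 20759334 to 28698625 reads over 18388 to 19985 genes. The 10 most abundant genes of each library took 15.8% to 20.2% of the reads in myocytes, 4.93% to 6.14% in endothelial cells and 5.21% to 9.03% in fibroblasts.

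Markers of the intended cell type were highest in every set of libraries, but markers of other types were present and moved with the groups. Endothelial markers stood in myocyte libraries at 4.97% ± 0.788 of their level in endothelial cells (SD, n = 3) in sham, 9.64% ± 3.11 at 1 week and 8.28% ± 1.01 at 8 weeks. Fibroblast markers stood in myocyte libraries at 1.29% ± 0.0879, 4.88% ± 0.855 and 6.12% ± 0.0901 of their level in fibroblasts. In endothelial libraries the fibroblast markers stood at 4.17% ± 1.06 in sham, 19.2% ± 3.77 at 1 week and 5.37% ± 0.777 at 8 weeks; these markers include Col1a1, Col1a2 and Col3a1. In fibroblast libraries the endothelial markers stood at 19.5% ± 1.02 in sham, 4.18% ± 1.54 at 1 week and 20.9% ± 8.48 at 8 weeks. Myocyte markers stayed at or under 0.359% in the other cells. Macrophage markers in fibroblast libraries had a mean log2(scaled reads + 1) of 7.20 in sham, 8.42 at 1 week and 6.68 at 8 weeks. Fibroblast markers stood there at 9.88, 9.77 and 9.31. Pericyte and smooth muscle markers in endothelial libraries stood at 7.81, 6.85 and 7.72. No libraries of these types exist, so their shares could not be computed. With 3 libraries against 3, the exact permutation tests of these marker levels could not go below 0.1.

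**Figure D1:**
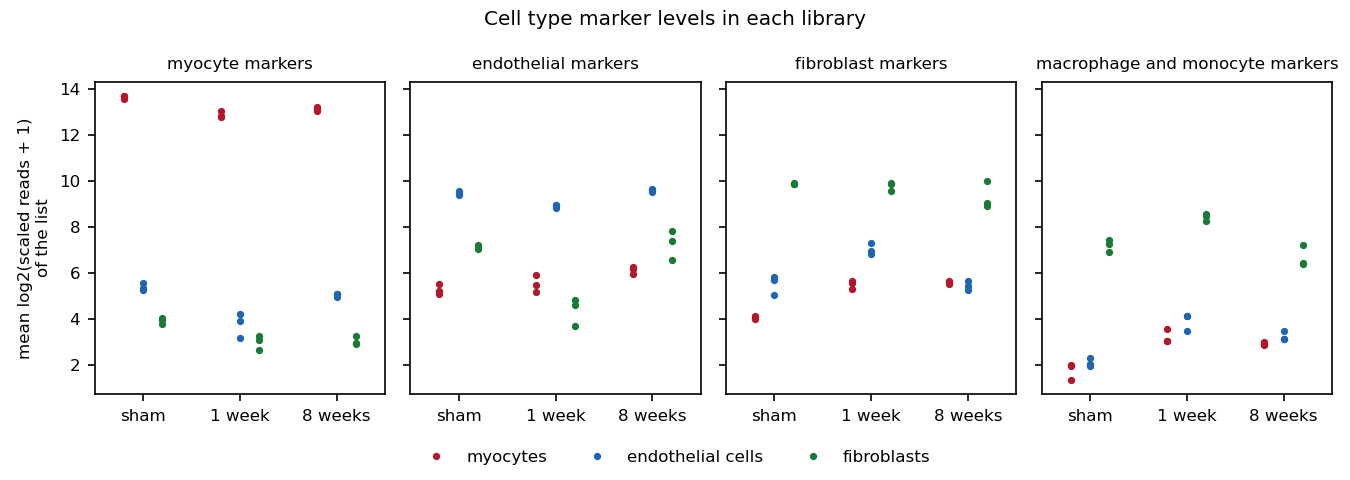
Each point is 1 library; the vertical axis is the mean log2(scaled reads + 1) of a marker list, the horizontal axis the group, and the color the cell type. Endothelial markers in fibroblast libraries were lower at 1 week, and fibroblast libraries at 8 weeks split, with fibroblast marker levels of 9.98, 9.05 and 8.89 in replicates 1, 2 and 3.

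Myocytes 1 week after TAC, against sham, showed the early response of the contractile cells to pressure load. Stress and fetal genes rose: Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, mm10 chromosome 4, 148000722 to 148002079), went from 256 ± 125 to 5270 ± 3513 scaled reads (SD, n = 3), 17.1-fold. Its log2 change of 4.10 was 4.92 without TAC replicate 1, which held 1308 scaled reads. Acta1, skeletal muscle actin (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), went from 370 ± 109 to 4977 ± 2266, 12.9-fold. Genes of calcium handling fell: Pln, the phospholamban that restrains the calcium pump of the sarcoplasmic reticulum (ENSMUSG00000038583, chromosome 10, 53337667 to 53345987), went from 23487 ± 285 to 10672 ± 679 scaled reads. Atp2a2, the pump itself (ENSMUSG00000029467, chromosome 5, 122453513 to 122502225), went from 47449 ± 1553 to 22260 ± 2320. Matrix genes were also higher in the myocyte libraries, with Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), going from 19.9 ± 0.157 to 353 ± 76.5 scaled reads, 16.7-fold.

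Of 26 tested hypertrophy and fetal genes, 18 were higher and 1 lower (adjusted p = 3.8e-16; adjusted p = 0.241 with an estimated correlation). Nppb, the brain natriuretic peptide, rose by 1.88 on the log2 scale (adjusted p = 0.0035), Ankrd1, a stress-responsive protein of the sarcomere, by 1.97 (6.68e-05). Myh7, the slow myosin heavy chain, rose by 3.10 (0.0212), a call lost without sham replicate 1 or 2, without TAC replicate 2 or 3, or with only the 6 compared libraries fitted. Without TAC replicate 1 it rose by 4.10. The other direction held for energy metabolism: 40 of 40 oxidative phosphorylation genes were lower (adjusted p = 4.75e-10; adjusted p = 0.499 with an estimated correlation). So were 26 of 28 fatty acid oxidation genes (1.56e-06; adjusted p = 0.499 with an estimated correlation) and 16 of 16 regulators of mitochondrial biogenesis (0.000313; adjusted p = 0.395 with an estimated correlation), the latter 11 with the median of ratios. Ion channel and calcium handling genes were lower for 24 of 29 (0.000481; adjusted p = 0.42 with an estimated correlation). Of 19 adult sarcomere genes 14 were lower, or 15 adjusted over the list alone (list adjusted p = 0.0825), whereas with the median of ratios 8 were lower and 3 higher. Of 21 glycolysis genes 3 were higher and 11 lower (0.908), a balance that turned to 7 higher and 6 lower with the median of ratios. Myh6, the fast myosin heavy chain, fell from 106864 ± 6351 to 56690 ± 4369 scaled reads (adjusted p = 1.68e-05). The strongest falls included Ces1d, a lipid hydrolase (192 ± 28.5 to 22.5 ± 4.42), Nr4a1, an immediate early transcription factor (148 ± 55.2 to 25.4 ± 14.0), with log2 changes of -3.05 and -2.55. The clock output genes Dbp (186 ± 24.1 to 24.4 ± 6.32) and Hlf (124 ± 10.6 to 16.0 ± 2.46) fell by 2.90 and 2.89.

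Of 45 fibrillar matrix genes, 41 were higher and 2 lower in the myocyte libraries (adjusted p = 1.2e-40; adjusted p = 0.171 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, rose 19.04-fold and Lox, which crosslinks collagen, 19.4-fold; Tnc rose 15.8-fold and Timp1, an inhibitor of matrix proteases, 8.98-fold. Of 42 cell cycle genes, 34 were higher and 1 lower (4.5e-25; adjusted p = 0.241 with an estimated correlation). Mki67, a mark of dividing cells, went from 21.4 ± 5.77 to 110 ± 44.8 scaled reads and Top2a from 8.96 ± 3.10 to 59.2 ± 26.3. Markers of other cells rose in the same libraries: 10 of 14 fibroblast markers were higher and 2 lower (7.08e-12; adjusted p = 0.201 with an estimated correlation). Macrophage markers were higher for 14 of 15 (1.39e-13; adjusted p = 0.241 with an estimated correlation) and mesothelium markers for 8 of 8 (2.82e-06; adjusted p = 0.241 with an estimated correlation). Of 24 interferon response genes 11 were higher, or 10 adjusted over the list alone (1.97e-08; adjusted p = 0.42 with an estimated correlation). Sprr1a, a small proline-rich stress protein, had 1 read over the sham libraries and 798 over the TAC libraries, a ratio of 648 with a counting interval of 116.0 to 25641.

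Of 13033 tested genes, limma called 8623 at 1 week, 1545 higher and 7078 lower (82.1% lower). This balance came with the deposited scale, under which the median gene changed by -0.34 log2. With scaling by the median of ratios 5424 genes were called, 2788 higher and 2636 lower, and with library totals 5260, 3845 higher and 1415 lower. The falls of Myh6, Atp2a2 and Pln stayed past the threshold after the median of ratios, at -0.56, -0.74 and -0.78 log2.

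**Figure D2:**
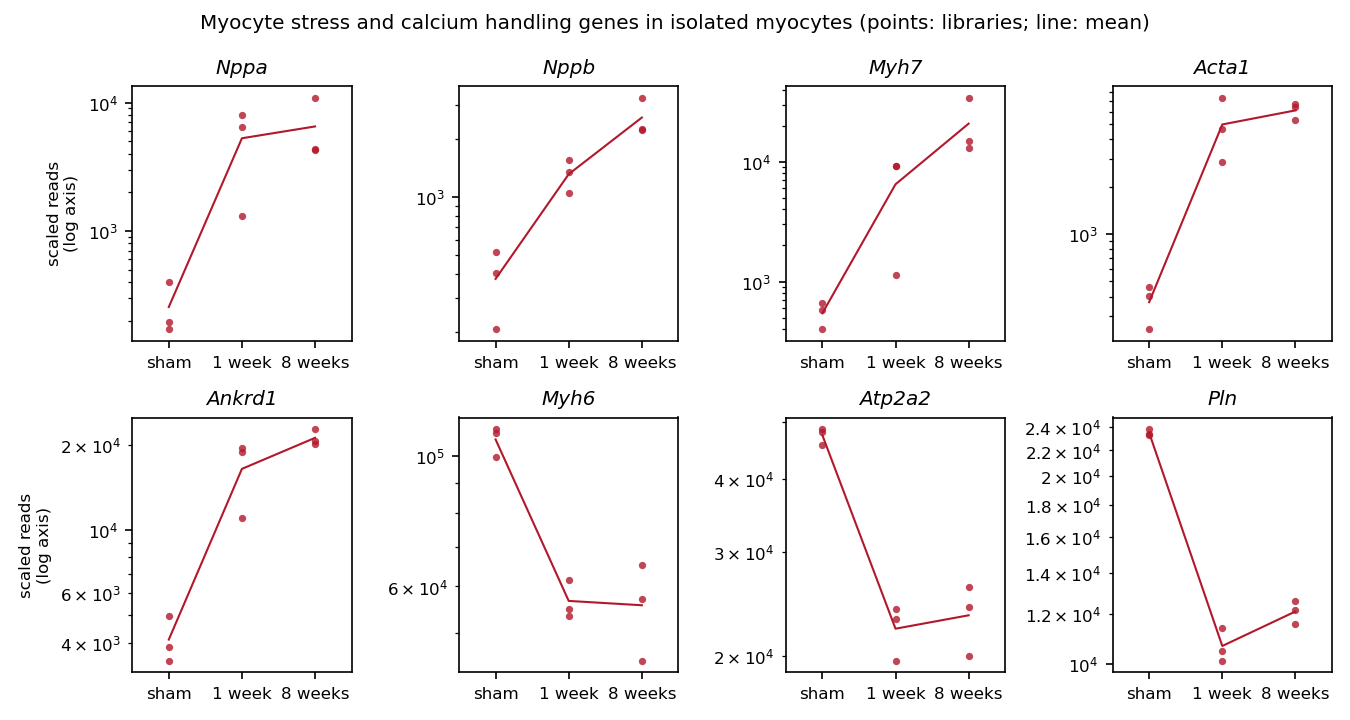
Scaled reads (vertical log axis) of 8 genes in myocyte libraries by group; points are libraries and lines join the means of 3 libraries. Nppa, Nppb, Myh7, Acta1 and Ankrd1 were higher and Myh6, Atp2a2 and Pln lower at both times, as in Pln at 23487, 10672 and 12126 scaled reads.

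Myocytes 8 weeks after TAC, against sham, showed the response to long pressure load. Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626) stood at 20823 ± 11757 scaled reads against 544 ± 132 in sham, 35.5-fold, and Nppa at 6513 ± 3824, 24.6-fold. Serpina3n, a secreted protease inhibitor (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), rose from 0.914 ± 0.587 to 88.6 ± 10.6 scaled reads, 48.1-fold, and Nmrk2, a kinase of NAD synthesis, from 5.58 ± 1.29 to 155 ± 63.2. Ctgf went from 120 ± 50.5 to 1808 ± 830 scaled reads and Tgfb2 from 19.1 ± 2.81 to 213 ± 54.4. Pln and Atp2a2 remained lower than in sham, at 12126 ± 512 and 23457 ± 3151 scaled reads, and Myh6 at 55735 ± 10320.

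Of 26 hypertrophy and fetal genes 22 were higher and 1 lower, or 23 and 1 adjusted over the list alone (adjusted p = 1.64e-15; adjusted p = 0.241 with an estimated correlation). Of 33 TGF-beta pathway genes 20 were higher and 5 lower, or 21 and 5 adjusted over the list alone (8.59e-08; adjusted p = 0.241 with an estimated correlation); the 5 were Tgfbr3, Ltbp1, Smad2, Smad3 and Smad4. Of 40 oxidative phosphorylation genes 39 were lower (1.03e-09; adjusted p = 0.499 with an estimated correlation). Of 28 fatty acid oxidation genes 22 were lower and 1 higher (7.95e-05; adjusted p = 0.528 with an estimated correlation). Of 24 oxidative stress genes 13 were higher and 4 lower (0.000931; adjusted p = 0.499 with an estimated correlation). Of 14 cytokine genes 10 were higher and 1 lower (1.03e-06; adjusted p = 0.241 with an estimated correlation), in libraries where 14 of 15 macrophage markers were higher (6.39e-08; adjusted p = 0.344 with an estimated correlation). Of 45 matrix genes 39 were higher and 3 lower (7.85e-27; adjusted p = 0.216 with an estimated correlation), with Col1a1 at 128 ± 1.52 scaled reads and Postn at 411 ± 72.1. In the same libraries 11 of 14 fibroblast markers were higher and 1 lower, or 12 and 1 adjusted over the list alone (1.13e-10; adjusted p = 0.216 with an estimated correlation). Endothelial markers were higher for 12 of 15 (6.39e-08; adjusted p = 0.42 with an estimated correlation). Of 42 cell cycle genes 2 were higher and 10 lower, or 1 and 8 adjusted over the list alone, and 3 and 6 with the median of ratios (0.416). Mki67 stood at 17.5 ± 3.08 scaled reads (adjusted p = 0.538). Cenpf, a kinetochore gene, fell from 201 ± 34.8 to 18.95 ± 2.37 scaled reads. Ces1d, Aqp4, a water channel, and Dbp fell by 3.82, 3.69 and 3.61 on the log2 scale, and Aqp4 by 2.94 without TAC replicate 3.

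At 8 weeks limma called 7384 of 13033 genes, 2070 higher and 5314 lower (72.0% lower), with a median change of -0.20 log2. With the median of ratios it called 6153, 3104 higher and 3049 lower, and with library totals 5990, 3168 higher and 2822 lower.

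The comparison of myocytes at 8 weeks with 1 week asks what changed as the load went on. Mki67, a mark of dividing cells, went from 110 ± 44.8 to 17.5 ± 3.08 scaled reads (log2 change -2.52, adjusted p = 0.00176) and Top2a from 59.2 ± 26.3 to 9.02 ± 2.23 (-2.51, 0.00264). Col1a1 fell by 1.44 on the log2 scale (1.16e-05) and Tnc by 2.32 (0.000222). Fkbp5, a partner of chaperones, rose from 15.9 ± 1.65 to 119 ± 38.5, and Fmo2, a monooxygenase, from 6.56 ± 0.961 to 58.4 ± 19.2. Ctgf rose by 2.26 on the log2 scale (0.0182), a call lost without TAC 1 week replicate 1 or TAC 8 weeks replicate 3. Tgfb2 rose by 1.24 (0.0297), a call lost without TAC 1 week replicate 2, without TAC 8 weeks replicate 1 or 3, or with only the 6 compared libraries fitted. Nppa (5270 ± 3513 against 6513 ± 3824, adjusted p = 0.67) and Myh7 (adjusted p = 0.14) did not pass. Limma called 3824 genes, 3032 higher and 792 lower (79.3% higher). With the median of ratios 2831 were called, 1491 higher and 1340 lower, and with library totals 3187, 786 higher and 2401 lower. Without TAC 1 week replicate 2 the count was 2485.

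Endothelial cells 1 week after TAC, against sham, bear on the question in the series title. Collagen genes rose: Col1a1 went from 77.1 ± 16.7 to 1472 ± 292 scaled reads (SD, n = 3), 18.9-fold, and Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) from 211 ± 26.3 to 2374 ± 354, 11.2-fold. Ltbp2, which binds microfibrils (ENSMUSG00000002020, chromosome 12, 84783212 to 84876532), rose 30.9-fold and Thbs4, a matricellular protein (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818), 25.9-fold. Cell division genes rose as well, with Mki67 going from 72.3 ± 17.7 to 389 ± 66.3 scaled reads and Top2a from 36.9 ± 9.97 to 213 ± 39.9. Kdr, the main VEGF receptor (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), fell from 3275 ± 399 to 2005 ± 335 scaled reads. Its call was lost with 27 libraries in 1 fit.

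Of 45 fibrillar matrix genes 40 were higher and 0 lower (adjusted p = 4.53e-31; adjusted p = 0.241 with an estimated correlation). Of 16 basement membrane genes 12 were higher and 1 lower (1.65e-07; adjusted p = 0.344 with an estimated correlation). Of 42 cell cycle genes 40 were higher and 1 lower (1.91e-36; adjusted p = 0.241 with an estimated correlation). Of 27 activated fibroblast genes 20 were higher and 4 lower (1.18e-12; adjusted p = 0.241 with an estimated correlation), with Postn at 2287 ± 730 scaled reads against 273 ± 31.0. In the same libraries 9 of 14 fibroblast markers were higher and 2 lower (1.43e-07; adjusted p = 0.367 with an estimated correlation). Macrophage markers were higher for 14 of 15 (8.21e-15; adjusted p = 0.241 with an estimated correlation).

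The mesenchymal list moved in both directions: of 31 genes 16 were higher and 9 lower, or 16 and 4 with the median of ratios (adjusted p = 4.73e-06; adjusted p = 0.241 with an estimated correlation). Collagens, Fn1 (750 ± 170 to 2004 ± 309 scaled reads), Vim, an intermediate filament of mesenchymal cells (1587 ± 153 to 3246 ± 98.8), Cd44 and Mmp14 were among the higher genes. The contractile genes Acta2 and Tagln fell, by 0.69 and 0.72 on the log2 scale (adjusted p = 0.000761 and 0.000262), calls lost with 27 libraries in 1 fit. They stood beside falls of 15 of 15 markers of pericytes and smooth muscle (3.98e-05; adjusted p = 0.344 with an estimated correlation), a list that holds both. Of the transcription factors that drive the transition, Twist1 rose from 3.32 ± 0.295 to 6.29 ± 1.94 scaled reads (0.00517) whereas Zeb2 was lower with the deposited scale (adjusted p = 0.018) and not called with the median of ratios (adjusted p = 0.18). Snai1 stood at 17.0 ± 2.44 and 16.3 ± 1.20 scaled reads (adjusted p = 0.703) and Snai2 at 32.2 ± 5.24 and 29.6 ± 2.96 (adjusted p = 0.42); both differences turned positive with the median of ratios, TMM or library totals. Of 31 endothelial identity genes 24 were lower, or 25 adjusted over the list alone, and 0 higher (adjusted p = 0.0012; adjusted p = 0.499 with an estimated correlation), whereas with the median of ratios 16 were lower and 4 higher. Cdh5, the endothelial cadherin, went from 2898 ± 340 to 2230 ± 100.999 scaled reads (-0.37 log2, adjusted p = 0.0097), a call lost with the median of ratios (-0.18), TMM, library totals or 27 libraries in 1 fit.

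Immediate early and dissociation stress genes were lower for 29 of 34 members and higher for 1, Myc (adjusted p = 1.75e-05; adjusted p = 0.407 with an estimated correlation). Whether TAC or the isolation of the cells gave this difference was not tested. The median of ratios gave 20 lower and 1 higher. Of 18 endothelial lipid transport genes 2 were higher and 11 lower, or 4 and 8 with the median of ratios (0.167). Of 20 endothelial activation genes 8 were higher and 3 lower, or 8 and 5 adjusted over the list alone (0.0123; adjusted p = 0.582 with an estimated correlation). Npr3, the natriuretic peptide clearance receptor, fell from 123 ± 18.2 to 26.1 ± 7.13 scaled reads and Cdkn1c, a cell cycle inhibitor, from 194 ± 6.40 to 41.6 ± 9.78. Myocyte markers fell for 15 of 15 genes (1.19e-05; adjusted p = 0.499 with an estimated correlation), Tnni3 among them, and hemoglobin transcripts fell by 2.29 (Hba-a1) and 2.32 (Hba-a2), a pair of near-identical genes whose reads may not be separable. Schwann cell markers were lower for 9 of 11 genes (0.0837). Of 5 neutrophil markers 0 passed (list adjusted p = 0.0222; adjusted p = 0.528 with an estimated correlation), and of 5 platelet markers 2 were higher (0.0176; adjusted p = 0.499 with an estimated correlation).

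Limma called 6765 of 13146 genes in endothelial cells at 1 week, 1628 higher and 5137 lower (75.9% lower), with a median change of -0.17 log2. With the median of ratios 5159 were called, 2708 higher and 2451 lower, and with library totals 5231, 3303 higher and 1928 lower.

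Endothelial cells 8 weeks after TAC stood closer to sham. Col1a1 was at 61.7 ± 7.56 scaled reads against 77.1 ± 16.7 in sham (adjusted p = 0.43), and Col3a1 was lower, at 130 ± 17.8 against 211 ± 26.3 (adjusted p = 0.0284). Macrophage genes were higher: Mrc1, a mannose receptor of tissue macrophages (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), went from 7.48 ± 1.08 to 30.8 ± 7.07 scaled reads, and Csf1r from 5.61 ± 1.67 to 19.1 ± 4.34. Npr3 (ENSMUSG00000022206, chromosome 15, 11839896 to 11907287), also a marker of the endocardium, remained lower, at 39.3 ± 5.88 scaled reads, and the imprinted H19 RNA fell from 247 ± 62.7 to 82.6 ± 20.7. Thbs4 was still higher, at 31.5 ± 7.75 against 5.03 ± 0.691 scaled reads (adjusted p = 0.0244). Fibroblast markers stood in these libraries at 5.37% of their level in fibroblasts, where Thbs4 was at 580 ± 247 scaled reads at 8 weeks, so RNA of fibroblasts was not excluded as its source. The muscle genes Acta1 (24.9 ± 1.01 against 3.44 ± 1.54) and Xirp2 (55.1 ± 11.2 against 14.98 ± 1.15) were higher in these libraries as well. Myocyte markers stood there at 0.359% of their level in myocytes, where Acta1 and Xirp2 were at 6116 ± 735 and 12816 ± 2858 scaled reads at 8 weeks, so carryover of myocyte RNA was not excluded as the source of these 2 calls.

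Of 15 macrophage markers 7 were higher, or 14 adjusted over the list alone (adjusted p = 2.43e-17; adjusted p = 0.241 with an estimated correlation). Of 7 lymphocyte markers 1 was higher, or 5 adjusted over the list alone (0.0105; adjusted p = 0.241 with an estimated correlation). Of 42 cell cycle genes 3 were lower (Top2a, Birc5 and Rrm2), or 24 adjusted over the list alone, and 0 higher (1.52e-17; adjusted p = 0.344 with an estimated correlation). Of 11 endocardium markers 4 were lower, or 7 adjusted over the list alone (2.25e-08; adjusted p = 0.171 with an estimated correlation). Of 8 markers of lymphatic endothelium 1 was higher and 1 lower, or 1 and 4 adjusted over the list alone (0.0115; adjusted p = 0.373 with an estimated correlation). Fibrillar matrix genes had 1 higher and 1 lower of 45, or 1 and 2 adjusted over the list alone (0.0053, down; adjusted p = 0.65 with an estimated correlation). Of oxidative phosphorylation genes 0 of 40 passed (list 8.51e-07, down; adjusted p = 0.499 with an estimated correlation). Limma called 195 of 13146 genes, 100 higher and 95 lower, and 2177 had an unadjusted p under 0.05. The count was 23 without TAC 8 weeks replicate 1, 24 without replicate 3, 115 without replicate 2, 102 without sham replicate 1 and 627 without sham replicate 3. Mrc1, Csf1r, Plagl1 and Asb4 stayed called in every alternative. So did Acta1 and Xirp2, but no alternative removed RNA of myocytes. Thbs4 and Top2a were each lost in 8 of them, H19 and Col3a1 in 5 and Npr3 in 1 (27 libraries in 1 fit).

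The comparison of endothelial cells at 8 weeks with 1 week asks whether the early change was transient. Col1a1 went from 1472 ± 292 to 61.7 ± 7.56 scaled reads (log2 change -4.54, adjusted p = 4.44e-07) and Col3a1 from 2374 ± 354 to 130 ± 17.8 (-4.18, 4.76e-08). Mki67 fell from 389 ± 66.3 to 41.2 ± 4.62 scaled reads (1.05e-06). Cthrc1, a secreted protein of activated fibroblasts, fell by 4.49 on the log2 scale and Tnc by 4.02. Kdr rose from 2005 ± 335 to 3976 ± 108 scaled reads (7.64e-05), and Cyp26b1, which degrades retinoic acid, from 14.3 ± 5.92 to 78.7 ± 6.11. The fibroblast marker share fell over the same interval from 19.2% to 5.37%. Limma called 7413 genes, 5632 higher and 1781 lower (76.0% higher), with a median change of 0.20 log2. With the median of ratios 5994 were called, 2820 higher and 3174 lower, and with library totals 5899, 2334 higher and 3565 lower.

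Fibroblasts 1 week after TAC, against sham, showed an activated state. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037) rose from 355 ± 104 to 9937 ± 3379 scaled reads (SD, n = 3), 27.6-fold, and Cthrc1 (ENSMUSG00000054196, chromosome 15, 39076932 to 39087121) from 0.913 ± 0.254 to 164 ± 92.0, 77.3-fold. Fn1, fibronectin (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), rose from 378 ± 35.6 to 4949 ± 1570 and Col1a1 from 1352 ± 167 to 6161 ± 744 scaled reads. Spp1, the cytokine-like protein osteopontin, rose 32.9-fold, in libraries where macrophage markers rose as well. Which cells it came from was not tested. Endothelial genes fell in the fibroblast libraries, Cdh5 (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511) from 532 ± 21.4 to 73.5 ± 29.3 scaled reads and Kdr from 640 ± 46.5 to 84.6 ± 34.2.

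Of 45 fibrillar matrix genes 27 were higher and 0 lower, or 27 and 1 adjusted over the list alone (adjusted p = 3.18e-09; adjusted p = 0.373 with an estimated correlation). Of 31 activated fibroblast genes 20 were higher and 2 lower, or 21 and 2 adjusted over the list alone (1.9e-07; adjusted p = 0.241 with an estimated correlation). Tagln, a contractile gene of myofibroblasts, rose from 41.9 ± 14.6 to 186 ± 172 scaled reads (adjusted p = 0.0329), a call lost without any 1 sham replicate, without TAC replicate 2 or with library totals. Acta2 stood at 173 ± 170 against 63.0 ± 24.2 (adjusted p = 0.184). Of 42 cell cycle genes 38 were higher and 0 lower, or 39 and 1 adjusted over the list alone (1.43e-20; adjusted p = 0.344 with an estimated correlation), and Mki67 went from 50.7 ± 18.8 to 226 ± 56.2 scaled reads. Of 25 quiescent fibroblast genes 3 were higher and 13 lower, or 3 and 14 adjusted over the list alone (0.000494; adjusted p = 0.557 with an estimated correlation). Inmt, a methyltransferase, fell from 71.4 ± 27.04 to 3.99 ± 1.34 scaled reads. Macrophage markers were higher for 12 of 15 genes, or 13 adjusted over the list alone (2.02e-06; adjusted p = 0.488 with an estimated correlation). Immediate early and dissociation stress genes were lower for 21 of 34, or 24 adjusted over the list alone (2.53e-07; adjusted p = 0.499 with an estimated correlation).

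Of 31 endothelial identity genes 28 were lower, or 30 adjusted over the list alone (adjusted p = 2.95e-19; adjusted p = 0.292 with an estimated correlation). Of 30 angiogenic sprouting genes 15 were lower and 3 higher, or 16 and 4 adjusted over the list alone (2.58e-05; adjusted p = 0.42 with an estimated correlation). The same libraries had 15 of 15 endothelial markers lower (2.58e-13; adjusted p = 0.344 with an estimated correlation), with Aqp1 falling by 3.75 and Car4 by 3.62 on the log2 scale. Of 23 unfolded protein response genes 6 were higher and 2 lower (0.15). Limma called 4256 of 13691 genes, 2394 higher and 1862 lower; the count was 2754 without sham replicate 1 and 2721 without TAC replicate 2. With the median of ratios 5536 were called, 3053 higher and 2483 lower, and with library totals 5570, 2694 higher and 2876 lower.

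**Figure D3:**
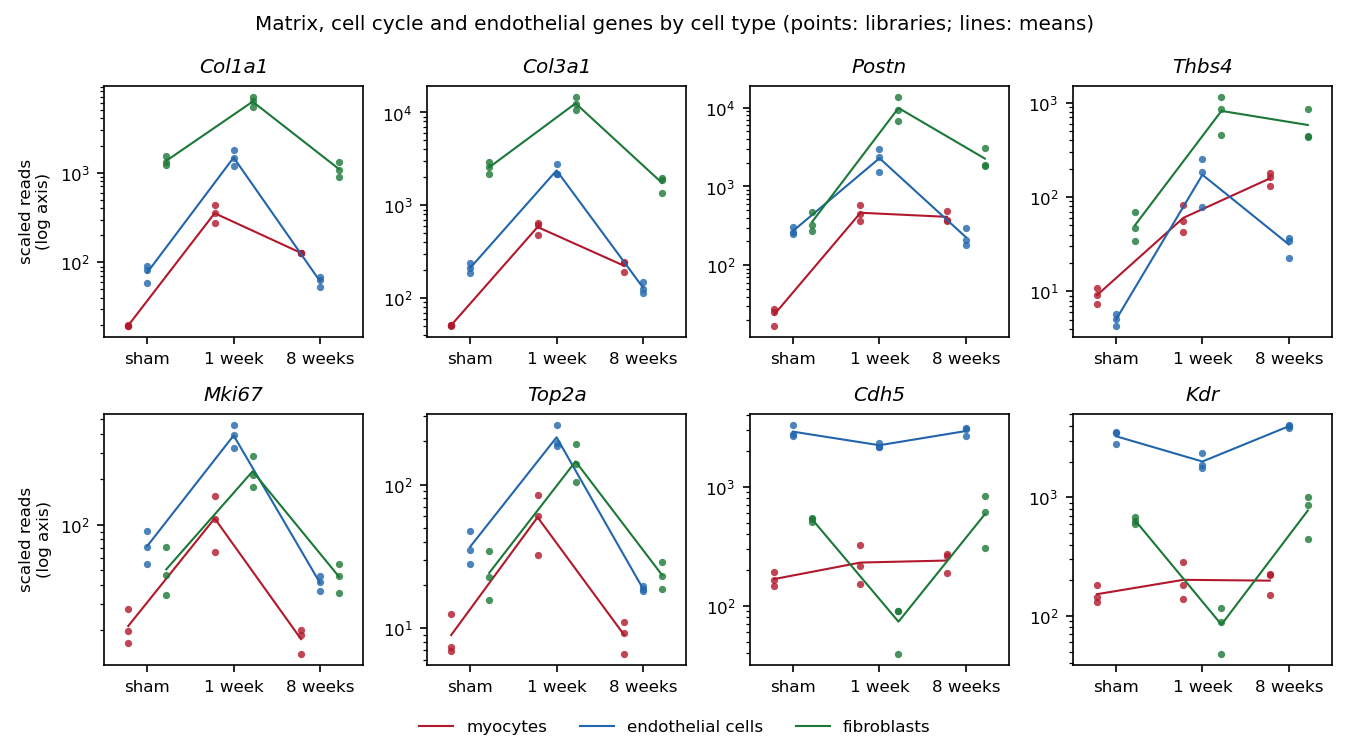
Scaled reads (vertical log axis) of 8 genes by group and cell type; points are libraries and lines join the means of 3 libraries, with a small horizontal offset per cell type. Col1a1 and Mki67 peaked at 1 week in all 3 cell types, and Cdh5 in fibroblast libraries went from 532 to 73.5 and 588 scaled reads.

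Fibroblasts 8 weeks after TAC, against sham, had several activation genes higher. Postn stood at 2260 ± 719 scaled reads against 355 ± 104 in sham, 6.32-fold, and Thbs4 at 580 ± 247 against 50.4 ± 18.1, 11.2-fold. Ctgf, a matricellular growth regulator (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), rose from 273 ± 29.4 to 1436 ± 117 scaled reads, and F2rl1, a receptor activated by proteases (ENSMUSG00000021678, chromosome 13, 95511732 to 95525227), from 2.64 ± 0.336 to 25.3 ± 3.12. Col1a1 was at 1093 ± 210 against 1352 ± 167 (adjusted p = 0.4) and Col3a1 at 1744 ± 326 against 2562 ± 375 (adjusted p = 0.177). Lepr, the leptin receptor, fell from 107 ± 35.8 to 17.99 ± 13.5 and Hspa1b, a heat shock protein, from 492 ± 199 to 85.5 ± 21.6 scaled reads.

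Of 31 activated fibroblast genes 9 were higher (with Meox1, Runx2 and Nox4 among them) and 3 lower, or 13 and 4 adjusted over the list alone (adjusted p = 1.94e-07; adjusted p = 0.241 with an estimated correlation). Of 45 fibrillar matrix genes 4 were higher and 4 lower, or 4 and 7 adjusted over the list alone (0.637). Of 25 quiescent fibroblast genes 1 was higher and 2 lower, or 1 and 10 adjusted over the list alone (0.00016; adjusted p = 0.528 with an estimated correlation). In the fit without TAC 8 weeks replicates 2 and 3, where 1 library stands for the group, the quiescent list did not pass (0.095) and the activated list did (0.00148). Of 34 immediate early and dissociation stress genes 6 were lower, or 14 adjusted over the list alone (1.11e-06; adjusted p = 0.523 with an estimated correlation). Of the 6, 5 encode heat shock proteins. Myocyte markers were lower for 9 of 14 genes, or 10 adjusted over the list alone (9.47e-09; adjusted p = 0.287 with an estimated correlation).

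Limma called 604 of 13691 genes, 319 higher and 285 lower. With the median of ratios it called 450, 185 higher and 265 lower, and with TMM 513, 172 higher and 341 lower. The balance was the other way with library totals (538, 322 higher and 216 lower) and without a filter (993, 679 higher and 314 lower). The libraries of this group stood apart from each other: replicate 1 had the largest distance to the others (0.568, against 0.356 and 0.319), and replicates 2 and 3 had the lower fibroblast and the higher endothelial marker levels. Without replicate 1 the count was 5181, without 2 it was 124, without 3 it was 152, and without both 2 and 3, where 1 library stands for the group and the spread comes from the other groups, it was 21. Leaving out sham replicate 1, 2 or 3 gave 203, 103 and 119. F2rl1, Crlf1, Cst6 and Dio2 passed in every alternative, and Postn, Thbs4, Ltbp2, Atp6v0a4 and Ctgf in each but the fit with 1 library at 8 weeks. Lepr, Hspa1b, Col6a6, Ccl11, Chad, Inmt, Cnmd and AI464131 were each lost in 3 or more alternatives.

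The comparison of fibroblasts at 8 weeks with 1 week asks how far activation subsided. Postn fell by 2.12 on the log2 scale (adjusted p = 0.000428) and Col1a1 from 6161 ± 744 to 1093 ± 210 scaled reads (3.84e-05). Ccr2, the receptor that recruits monocytes, fell from 177 ± 58.7 to 12.3 ± 3.02. Ctgf stood at 1228 ± 558 and 1436 ± 117 (adjusted p = 0.378), a difference of 0.32 log2 whose sign turned without TAC 1 week replicate 1. Cdh5 rose from 73.5 ± 29.3 to 588 ± 267 scaled reads (0.000326), C1qtnf9 from 9.26 ± 3.84 to 129 ± 57.8, and Myh11, the smooth muscle myosin, from 12.5 ± 5.94 to 165 ± 61.3. The endothelial marker share went over the same interval from 4.18% to 20.9%. Limma called 5818 genes, 2205 higher and 3613 lower (62.1% lower). With library totals it called 6648, 4126 higher and 2522 lower, and without TAC 8 weeks replicates 2 and 3, which leaves 1 library of that group, it called 3233.

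**Figure D4:**
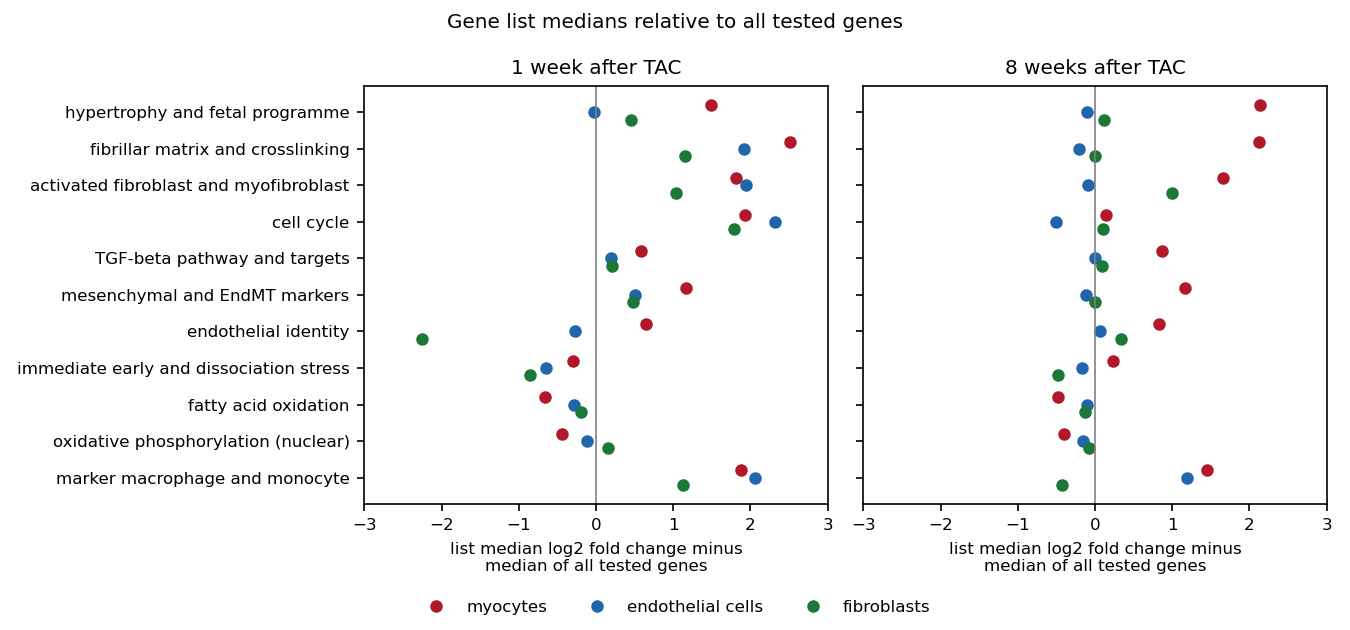
Each point is the median log2 fold change of a gene list against sham minus the median of all tested genes (horizontal axis), for 11 lists (rows), at 1 week (left) and 8 weeks (right), by cell type. Fibrillar matrix genes lay at 2.51, 1.92 and 1.16 in myocytes, endothelial cells and fibroblasts at 1 week, and at 2.12, -0.21 and 0.00 at 8 weeks.

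The response to TAC differed between the cell types. Cdkn1a, an inhibitor of the cell cycle (ENSMUSG00000023067), rose in myocytes from 7.78 ± 0.538 to 38.3 ± 5.39 and 133 ± 31.4 scaled reads at 1 and 8 weeks. It fell in endothelial cells at 1 week from 543 ± 74.8 to 292 ± 32.5 (interaction adjusted p = 1.41e-10). Tnfaip8, a regulator of cell death, fell in myocytes from 270 ± 4.36 to 94.2 ± 5.40 and rose in fibroblasts from 37.5 ± 7.81 to 93.2 ± 13.1 at 1 week (2.42e-10). At 8 weeks the muscle genes Fhl1 (143 ± 8.09 to 844 ± 108 in myocytes) and Mylk4 (1333 ± 86.1 to 261 ± 46.4) and the clock gene Arntl (8.32 ± 0.906 to 55.6 ± 2.92) were among the 8 genes with the lowest interaction p. Of 13887 genes, the effect differed between cell types for 8263 at 1 week, of which 1889 were called in opposite directions, and for 6039 at 8 weeks. These counts hold for the deposited scale: with the median of ratios within each cell type they were 6524 (5553 of them shared), 1262 and 5573 (4617 shared).

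Calls were shared between cell types at 1 week. Endothelial cells and fibroblasts shared 966 higher genes, with 275 under independence (odds ratio 12.4), and 1376 lower genes, with 691 under independence (odds ratio 7.15). Myocytes and endothelial cells shared 690 higher genes (173 under independence, Fisher's exact adjusted p = 3.88e-304) and 3069 lower genes (2636; 8.27e-59). Myocytes and fibroblasts shared 631 higher (248; 6.86e-143) and 765 lower, fewer than the 923 under independence (odds ratio 0.646; 1.61e-16). Higher in all 3 cell types were 465 genes and lower 631. At 8 weeks these numbers were 9 and 9. Myocytes and endothelial cells then shared 61 higher genes (13.9 under independence; 2.14e-29) and 28 lower (34.5; 0.165). Myocytes and fibroblasts shared 82 higher (30.8; 1.19e-18) and 95 lower (89.1; 0.446), and endothelial cells and fibroblasts 12 higher (1.38; 1.46e-08) and 17 lower (1.69; 8.8e-13). These tests run across genes, which are not independent replicates, and on the deposited scale alone. At 1 week fibroblast markers went from 4.17% to 19.2% in endothelial libraries and from 1.29% to 4.88% in myocyte libraries. Macrophage markers stood higher by 1.45, 1.81 and 1.22 log2 in myocyte, endothelial and fibroblast libraries. RNA of the same other cells was therefore not excluded as a source of higher genes shared at 1 week.

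Calls at 1 and 8 weeks coincided most in myocytes, where 5903 genes were called at both times in the same direction and 123 in opposite directions. Of the 5903, 1125 were higher and 4778 lower, with 245 and 2886 under independence. Overlaps were counted on the deposited scale alone, under which the median myocyte gene changed by -0.34 and -0.20 log2. With the median of ratios only 2636 myocyte genes were lower at 1 week and 3049 at 8 weeks, so 4778 could not be shared there. In endothelial cells 118 were called both times in the same direction (65 higher, 12.4 under independence; 53 lower, 37.1 under independence) and 36 in opposite directions. In fibroblasts these were 257 (105 higher, 55.8 under independence; 152 lower, 38.8 under independence) and 24. Across genes, the fold changes at the 2 times correlated with Pearson r of 0.80 in myocytes, 0.10 in endothelial cells and 0.09 in fibroblasts, beside 0.50, 0.51 and 0.50 in simulated groups that did not change but shared the sham libraries. The covariances were 0.342, 0.0136 and 0.0291 beside simulated 0.0130, 0.00876 and 0.0190. The simulated groups shared 0 calls, but 3 sham libraries cannot be divided into separate control sets for the 2 times, so part of an excess can come from the shared controls.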

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

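The contrasts between cell types and between the 2 TAC times stood apart because the response differed between the groups in many genes. Cdkn1a, Sprr1a and Carhsp1 had among the lowest p-values for a TAC effect that differed between cell types at both times, and Arntl, a core clock gene, joined them at 8 weeks. The genes named below were chosen after their p-values were seen, as the 8 named genes with the lowest p at each time.

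The TAC effect differed between cell types for 8263 genes at 1 week and 6039 at 8 weeks. Samples of 8 weeks differed from those of 1 week for 3824 genes in myocytes, 7413 in endothelial cells and 5818 in fibroblasts. At 1 week the lowest adjusted p-values for a difference between cell types belonged to Sprr1a (4.78e-11), Cdkn1a (1.41e-10) and Tnfaip8 (2.42e-10). They were followed by Carhsp1 (1.46e-09) and Ano10 (2.54e-09), and by Ttll1, Cyfip2 and Mdga1, each at 2.93e-09. Cyfip2 and Mdga1 fell in myocytes, from 1013 to 522 and from 43.4 to 17.1 scaled reads, and in fibroblasts went from 4.70 to 13.7 and from 6.28 to 17.0.

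At 8 weeks the lowest belonged to Cdkn1a (3.28e-14), Sprr1a (1.16e-11), Nmrk2 (2.5e-11) and Carhsp1 (5.33e-11). Fhl1 (9.36e-11), Mylk4 (2.52e-10), Lrp8 (2.77e-10) and Arntl (3.17e-10) came next. Most of these are differences between myocytes and the other cells: Lrp8 went in myocytes from 1.22 to 29.7 scaled reads and in endothelial cells from 0.5003 to 0.595.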

How the results depend on the processing

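The count of myocytes at 1 week moved with scaling, and those of endothelial cells and fibroblasts at 8 weeks with single libraries. Which alternatives to add was partly chosen after results were seen; TMM, voom, the deposited log2 values and the fit without fibroblast replicates 2 and 3 of 8 weeks are such additions. Those replicates were chosen after their values were seen, although replicate 1 lay farther from the others, and the data do not tell which are right.

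Myocytes at 1 week had 5424 calls with the median of ratios, 5260 with totals and 5383 with TMM, and 7604 to 8680 with 1 library left out. Myocytes at 8 weeks ranged from 6268 to 6907 with 1 library left out, and 8 weeks against 1 week from 2485 (without TAC 1 week replicate 2) to 4363. Endothelial cells at 1 week ranged from 5150 to 7005 and 8 weeks against 1 week from 6026 to 6795. At 8 weeks endothelial cells had 115 calls with at least 10 scaled reads and 80 with 27 samples in 1 fit, and from 23 (without TAC 8 weeks replicate 1) to 627 (without sham replicate 3).

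Fibroblasts at 1 week had 7156 calls by the authors' FDR over all listed genes, 6248 of them among the 13691 genes tested here, and 2721 (without TAC replicate 2) to 3854 with 1 library left out. Fibroblasts at 8 weeks had 993 calls without a filter, 262 with at least 10 scaled reads, 247 with the 6 samples, 2281 with 27 samples, 311 with a pseudocount of 5, 338 with voom, 957 on the deposited log2 values, 899 with replicate numbers as blocks, and 21 without replicates 2 and 3, a fit with 1 library in that group. By the authors' FDR 6409 of all listed genes passed, 3203 of them among the 13691 tested here. Leaving out 1 library gave 103 (without sham replicate 2) to 5181 (without TAC 8 weeks replicate 1). The 8 week against 1 week contrast had 3806 with at least 10 scaled reads, 3233 without replicates 2 and 3 (1 library left at 8 weeks) and 4098 to 8241 with 1 library left out. The difference between cell types ranged over left-out libraries from 7494 to 8263 at 1 week and from 5099 to 8183 at 8 weeks. Under the median of ratios it was 6524 (within each cell type) or 6733 (over 27 libraries) at 1 week and 5573 or 5498 at 8 weeks, and without fibroblast replicates 2 and 3 of 8 weeks 9039 and 6252. Opposite calls at 1 week were 1262 or 1300 with the median of ratios and 1318 to 1959 with 1 library left out. At 8 weeks, where 397 were opposite, they were 489 or 513 with the median of ratios, 222 and 257 without fibroblast sham replicate 2 or 3, and 1079, 171 and 190 without fibroblast TAC replicate 1, 2 or 3.

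Of 186 results for named genes in 3582 alternatives, 3431 stayed, 130 were weaker, 10 stronger and 11 reversed. None of the reversed had passed. In endothelial cells at 1 week Snai1 was at 0.13 (median of ratios), 0.19 (totals) and 0.13 (TMM), with 0.0358 without sham replicate 1, 0.00 without TAC replicate 1 and -0.16 without sham replicate 3. Snai2 was at 0.0772, 0.14 and 0.0767, and from -0.20 (without sham replicate 1) to 0.0132 (without sham replicate 3). Nppa in myocytes at 8 weeks against 1 week ranged from -0.30 (without TAC 1 week replicate 1) to 1.01 (without replicate 2), and Ctgf in fibroblasts was lower by 0.00377 without TAC 1 week replicate 1 and higher by 0.66 without replicate 2.

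With an estimated correlation 0 of 121 list calls and 0 of 39 marker calls stayed. The self-contained test turned the direction of lists that had mostly failed. In myocytes at 1 week these were endothelial lipid transport (adjusted p = 0.0207), oxidative stress (0.16) and Schwann cells (0.333). At 8 weeks they were glycolysis (0.239), lipid transport (0.978), cell cycle (0.57), interferon (0.548, and 0.945 with blocks), unfolded protein response (0.918) and Schwann cells (0.978). In endothelial cells at 1 week they were hypertrophy (0.387), glycolysis (0.289), sprouting (0.266), interferon (0.57), unfolded protein response (0.418) and oxidative stress (0.282). At 8 weeks they were endothelial activation (0.776) and unfolded protein response (0.959), with activated fibroblast genes turned by blocks (0.953). In fibroblasts they were fibroblast (0.269) and mesothelium (0.98) markers at 1 week. At 8 weeks they were mitochondrial biogenesis (0.646), matrix (0.805), cell cycle (0.98) and Schwann cells (0.713).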

Other observations

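The circadian clock changed in myocytes in a patterned way. Arntl, an activator of the clock, rose from 8.32 to 30.6 and 55.6 scaled reads at 1 and 8 weeks, while its output gene Dbp fell from 186 to 24.4 and 14.3. In endothelial cells both moved the other way at 1 week: Arntl fell from 79.2 to 56.7 scaled reads (adjusted p = 0.00545) and Dbp rose from 2.82 to 5.19 (0.035). At 8 weeks they stood there at 84.5 and 1.05 scaled reads, and 0 of 13 clock genes were called. In fibroblasts Arntl stood at 91.2, 97.4 and 108 scaled reads and Dbp at 3.17, 3.91 and 1.98, with no call of either.

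Single macrophage genes were read in each cell type, without a test of their courses. Ccr2, carried by recruited monocytes, went in fibroblast libraries from 15.3 to 177 and 12.3 scaled reads and in endothelial libraries from 0.709 to 4.91 and 1.50. Mrc1, typical of resident macrophages, went in endothelial libraries from 7.48 to 30.8 at 1 week and stood at 30.8 at 8 weeks. In myocyte libraries Mrc1 went from 9.22 to 28.4 and 24.1 scaled reads, Csf1r from 6.83 to 20.6 and 15.4 and Cd163 from 3.89 to 6.79 and 11.2. Cenpf fell in myocytes from 201 to 51.8 and 18.95 scaled reads, but rose at 1 week in endothelial cells, from 15.8 to 88.8, and in fibroblasts, from 7.45 to 40.4.

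Of the tests below, those of the authors' scaling, of the endothelial matrix and cell cycle rises and of the clock were chosen after the results were seen. Those of the myocyte matrix and cell cycle rises were set after the list results but before their ratios were computed, and those of the regroupings and of abundant genes before.

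Whether the excess of lower genes in myocytes at 1 week comes from the deposited scaling was not settled. Of called genes 82.1% were lower on that scale and 26.9% with library totals, which follows from the shift of the median gene by 0.4618 log2 between the scales and does not show which of them is right. A few abundant genes do not account for the gap between these scales, because totals without the 100 most abundant genes, which held 39.5% of sham reads and 37.6% of TAC reads, gave 33.1%. No measurement of RNA content per cell is in the data, so whether it plays a part cannot be told.

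Matrix genes in endothelial cells and myocytes at 1 week might be RNA of fibroblasts. If the matrix rise in endothelial cells came from fibroblasts of the profile measured at 1 week, 18.9% of such RNA would be needed, against 3.66% by 8 other fibroblast markers, a ratio of 5.17 (3.86 to 9.53 over libraries). The same ratio was 36.4 (16.9 to 88.0) for the endothelial cell cycle rise and 2.81 (2.41 to 3.54) for matrix genes in myocytes (5.08% against 1.81%). Cell cycle genes in myocytes rose 6.12 times (4.55 to 16.0) as much as the marker shares of fibroblast and endothelial RNA would bring. The endothelial cell cycle rise would need 133% (107 to 167 over libraries) of the average fibroblast profile, which argues against such RNA as its source. The remaining ratios do not exclude it. The subtracted sham levels already held fibroblast RNA, which lowers the share given by markers that did not rise in fibroblasts. All 14 fibroblast markers, collagens included, stood at 4.88% in myocytes and 19.2% in endothelial cells, beside the 5.08% and 18.9% needed by matrix genes. This nearness decides nothing, because the 14 are summed with collagens that are themselves matrix genes. Their share is also a level and not a rise over sham. The median share of a single marker was 4.42% in myocytes and 13.7% in endothelial cells. A fibroblast subset richer in matrix or dividing more than the average could still give these rises. RNA of macrophages was not tested as a source. Their markers stood higher than in sham by 1.81 log2 in endothelial and 1.45 log2 in myocyte libraries.

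The clock change in myocytes may reflect another time of collection. Over 13 clock genes the median signed change was 1.66 and 1.19 in myocytes at 1 and 8 weeks, -0.37 and 0.08 in endothelial cells and -0.02 and 0.23 in fibroblasts. In myocytes 12 of the 13 were called in the direction of the pattern at each time, Clock being the exception at 1 week and Per1 at 8 weeks. Most of the 13 fall in that pattern. Of all 13033 tested myocyte genes, 7078 were called lower at 1 week and 5314 at 8 weeks on the deposited scale. The repressor and output genes of the clock had median changes of -1.73 and -1.26 log2, beside -0.34 and -0.20 for all genes. In endothelial cells at 1 week 3 of the 13 were called in the direction of the pattern and 5 against it. Another time of day would move all cells of a heart, and the value of that test, 0.193, leaves the question undecided, as whether the cell types came from the same hearts is not stated.

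Regroupings of the samples tested whether chance gives results of this size. For each of the 9 contrasts within a cell type, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The highest other split called 3 genes for myocytes at 1 week, against 8623, and 0 for each other contrast (7384, 3824, 6765, 195, 7413, 4256, 604 and 5818). The difference between cell types at 1 week, 8263 genes, was reached by 1 of 100 regroupings, the real one, with 5348 the highest other. Only 10 of the others left the myocyte split whole, and 2197 was the highest with it broken. Regrouping also broke the TAC effect within each cell type, so it does not test whether that effect was equal across cell types. At 8 weeks 6 of 100 reached 6039, with 7101 the highest other, so chance was not excluded. The 5 others were all among the 14 draws that left the myocyte split whole, and 370 was the highest with it broken, a division made after the 6 were seen. The count at 8 weeks thus follows the myocyte groups, a structure of the samples.

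For gene lists 4 of 100 regroupings, the real one included, gave 121 calls or more (highest other 123). For marker lists 4 of 100 gave 39 or more (highest other 40). Both shares lay under 0.05, but other groupings passed as many lists as the real one, so these counts do not exclude chance. A shorter set of 60 regroupings had been seen before the 100 were drawn. The overlap of the 2 times, 6278 genes, was reached by 1 of 100 (highest other 5604). These regroupings moved libraries between all groups of a cell type and so broke the TAC effects too. The share therefore does not test whether the 2 times overlap more than their calls and shared sham libraries would bring. The overlap between cell types, 7792, was reached by 1 of 100 (highest other 0), which tests nothing about the overlap, because splits that broke the groups of a cell type called 0 to 3 genes.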
